A study of Mus musculus with 12 samples.

How the data were processed

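Polyadenylated RNA was measured in 12 libraries of immortalized mouse embryonic fibroblasts without functional Maff, Mafg and Mafk, in 4 groups of 3 (mock or T-N2G cells, each with vehicle or 100 µM DEM for 12 h). The labels give RNeasy Mini for extraction, the SureSelect strand-specific kit for libraries, and medium with 10% serum. Per the submitters' processing notes the software was bcl2fastq 2.16.0.10, TopHat2 2.0.8b and Cuffdiff 2.1.1, and the genome build was mm9. The notes give no role or order of the tools, no strand setting and no gene annotation.

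The deposited table gives each gene an estimated count of fragments per library, which the file headers name raw fragments. They were taken as not scaled between libraries, since the scaled columns of the same table equal them times 1 factor per library. Of its 291816 gene and library values 98.3% were whole numbers (tolerance 0), and 917 of the 24318 genes had at least 1 value that was not whole. The table also gives FPKM per gene and library, fragments scaled by transcript length and library size as the authors deposited them. Its 2 other value columns per library, fragments after scaling, were not used. A status of FAIL stood in 37 gene and library values of 17 genes, 15 of them tested and none named, and these genes were kept. Library totals, summed over genes, were 18863560 to 23095692 fragments. Conditions and replicates of the table were joined to sample titles by the key in the series description. Genes are named by the symbols in the table. The reference table (GRCm38.p6) is of another build, so it served for gene names and neighbours only and no coordinate is given.

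Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 12469 genes to test and took out 11849, of which 6658 had no fragment in any library. TMM factors lay between 0.980 and 1.028. All 12 libraries entered 1 quasi-likelihood fit with a coefficient per group, and 5 contrasts were tested, those of T-N2G with mock cells in vehicle and in DEM, those of DEM with vehicle in mock and in T-N2G cells, and the difference of the latter. Benjamini-Hochberg adjusted p under 0.05 over all tested genes was a call. The common biological coefficient of variation was 0.110, with 8 residual degrees of freedom and a prior of 3.88. CPM used effective library sizes. A gene at 0 in all libraries of a group got a lower bound of its fold from 3 counts over that group, and bounds cover counting error only.

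The 38 gene lists, of stress responses, metabolism, matrix and cell type markers, were tested with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists with at least 3 tested members), with camera at an estimated correlation, and with fry. Beside the calls over all genes each list has the number of calls adjusted over the list alone. A list with no result for a comparison had no called set test there with or without the block, and a direction not given for a list had no called member.

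The tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names Maff, Mafg, Mafk and Nfe2l2 in every case. Per contrast it names the 8 largest positive and 8 largest negative log2 fold changes among called genes with at least 2 CPM in the higher group and no overlap between the 3 libraries of one group and the 3 of the other, which chance gives to 10% of genes. For the difference of DEM effects only the call and the level applied. Per list and contrast it names up to 4 called members with the smallest adjusted p, at least 1 of them of the rarer direction, and of a list without a call the most abundant member. A gene named in 1 contrast could be given with its values in others, and the genes that pass the rule were not all printed. Cgnl1, Cyb5a, the Y-linked genes and the imprinted genes were chosen after their values were seen.

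Replicate numbers are in the sample titles, and the labels do not say what they stand for. Whether they pair the libraries was checked from the deviations of log2 CPM from the group means, before the fits were compared. The 18 pairs of libraries with the same number had r between 0.361 and 0.631 (median 0.483) and the 36 pairs with different numbers between -0.422 and -0.00363, and each of the 12 libraries correlated best with its own number, so the numbers pair the samples. A fit with the replicate number as a block (coefficient of variation 0.0428, 6 residual degrees of freedom) was an alternative set before, and its values stand beside results whose call it changed or whose count it moved by over 1.5 times. The exceptions are counts by unadjusted p and calls adjusted over a list alone, given without the block. Counts of at least 2-fold with the block are given with the alternatives only. The first 4 principal components held 32.3, 20.0, 16.4 and 11.5% of the variance. Counts of replicate libraries were compared to check for the same library under 2 names, and the chi-square per degree of freedom was 9.96 to 26.8.

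Further alternatives were RLE scaling, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), limma on log2(FPKM + 1), on log2(FPKM + 0.1) and on genes at 1 FPKM in 3 libraries, a fit of only the groups compared, a robust spread, Nfe2l2 and Mafg left out, replicates 1 and 2 alone, and each library left out in turn. Added after the data were seen were the block with replicates 1 and 2 alone, an estimated correlation with the block, a test of group by series of library codes, and, for the agreement of effects, the DEM effects and each replicate number left out. The gene test was tested on simulated data for T-N2G over mock cells in vehicle (12383 genes tested). Genes to change were drawn from those with a mean of at least 2 CPM, so recovery below that level was not measured. The test recovered 68 of 100 genes changed 1.5-fold and 95 of 100 changed 2-fold, with 5 false calls, or 69, 94 and 2 with the block. These data had no replicate effects. With those of the libraries added after the data were seen (12408 genes tested), 63 and 85 were recovered with 0 false calls, or 91 and 99 with 7 with the block. No exon, isoform or allele was measured, and fragments of near-identical genes were left as the table assigns them.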

Results

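RNA was sequenced from immortalized mouse embryonic fibroblasts that lack the 3 small Maf genes Maff, Mafg and Mafk. Small Maf proteins are the partners with which Nrf2, the product of Nfe2l2, binds DNA and induces genes against oxidative and electrophilic stress. Mock cells were compared with cells that expressed T-N2G, an Nrf2-MafG heterodimer joined by a tether. Both were given vehicle or 100 µM diethyl maleate (DEM), an electrophile that binds glutathione, for 12 h. The 4 groups of 3 libraries each are called mock vehicle, mock DEM, T-N2G vehicle and T-N2G DEM. Library totals lay between 18863560 fragments in T-N2G DEM replicate 3 and 23095692 in mock DEM replicate 3, and 14799 to 15125 genes per library had a fragment. The labels do not say whether replicates were separate cultures. Levels are CPM, fragments scaled by the effective library size, as mean ± SD over n = 3 libraries per group. Log2 fold changes, between groups of n = 3, carry an approximate standard error. It is the size of the log2 fold change divided by the square root of edgeR's F statistic, from the fit of all 12 libraries. Adjusted p values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from limma's camera. Every called gene picked by the naming rule had its direction in each of the 3 pairs of libraries with the same replicate number. For genes named by largest fold, besides those for the difference of DEM effects, the rule forces this by requiring no overlap. For the other called genes, picking by call and adjusted p or fold in the same libraries favours it. The shared direction is therefore no separate support. The word block stands for the fit with the replicate number as a further term. Values with no such mention come from the fit without this term, set as the main fit before the data were examined. That fit takes libraries of the same number as unpaired, although the numbers pair them.

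The targeted and introduced genes were examined first. Mafg stood at 0.514 ± 0.0394 CPM in mock vehicle and 0.877 ± 0.0563 in mock DEM, against 137 ± 27.9 in T-N2G vehicle and 121 ± 22.2 in T-N2G DEM. It was 264-fold higher in T-N2G than in mock cells in vehicle (log2 8.04 ± 0.24, adjusted p = 5.96e-09) and 138-fold in DEM (log2 7.10 ± 0.23, adjusted p = 1.04e-08). Nfe2l2 stood at 53.2 ± 5.56 and 62.4 ± 3.79 CPM in the mock groups and at 599 ± 109 and 556 ± 94.5 in the T-N2G groups, 11.3-fold higher in vehicle (adjusted p = 3.15e-07) and 8.90-fold in DEM (adjusted p = 1.62e-07). All 6 T-N2G libraries lay above all 6 mock libraries for both genes, as their labels state. Maff had 4.06 ± 0.645 CPM in mock vehicle and 4.49 ± 0.700 in T-N2G DEM, and Mafk 2.04 ± 0.254 and 2.22 ± 0.319. Fragments are summed per gene and do not separate deleted exons from the rest, so these levels check nothing about the deletions, and the Nfe2l2 and Mafg fragments of T-N2G cells do not separate transgene from endogenous RNA. Mafg under DEM in mock cells had a log2 fold change of 0.76 ± 0.40 and an adjusted p of 0.229, or 0.0379 with the replicate block (0.0261 to 0.442 over all alternatives). In T-N2G cells it was -0.18 ± 0.15 with an adjusted p of 0.442, or 0.00816 with the block (0.00816 to 0.896 over all alternatives).

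**Figure D1:**
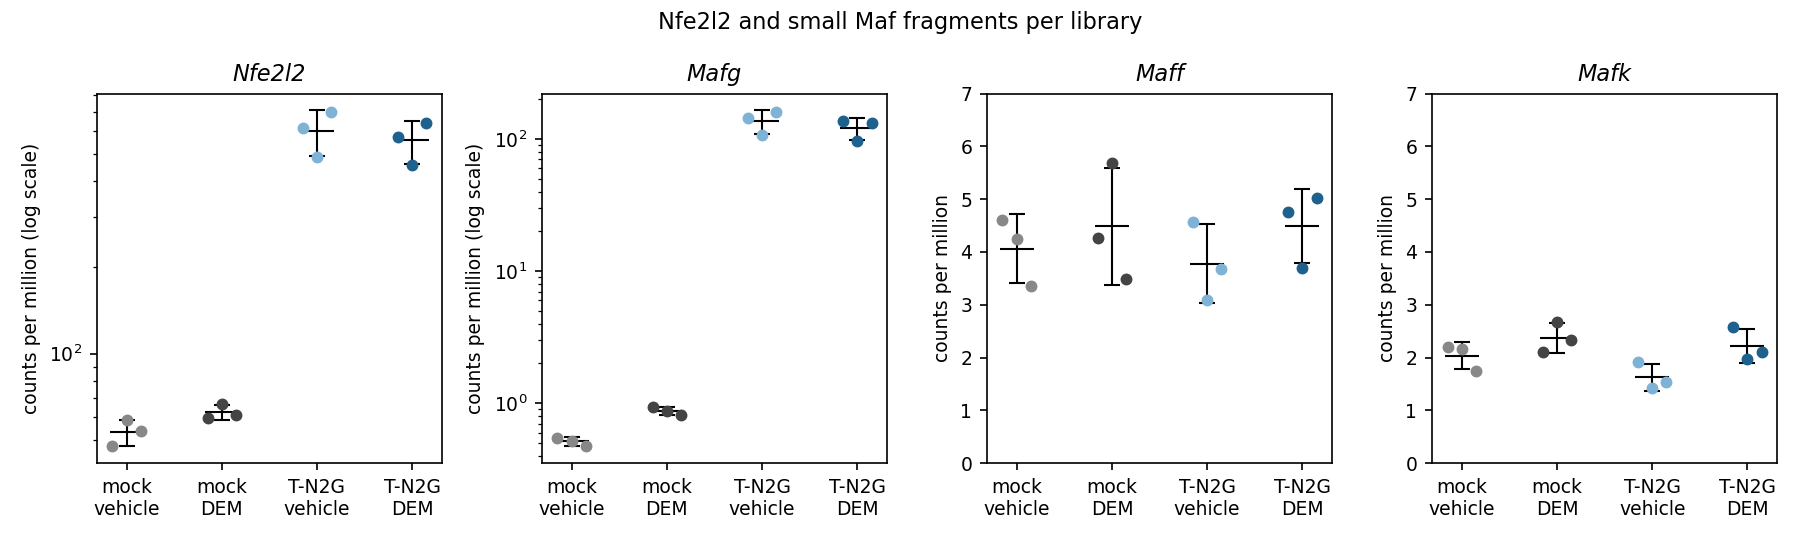
CPM of Nfe2l2, Mafg (log axis), Maff and Mafk per library (points) with the group mean (bar) and SD in the 4 groups of 3 libraries. Mafg means were 0.514 and 0.877 CPM in mock cells and 137 and 121 in T-N2G cells.

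The first comparison asked which genes differ between T-N2G and mock cells without an electrophile. Y-linked genes, described further below, were higher in T-N2G cells, so the populations may differ in composition besides T-N2G. A difference between them need not come from T-N2G. Genes called higher included members of the lists of glutathione conjugation and of heme and iron handling. Gsta4, a glutathione S-transferase, rose from 1.33 ± 0.757 to 20.7 ± 6.98 CPM, 15.3-fold (log2 3.94 ± 0.35, n = 3, adjusted p = 0.000454). The iron exporter gene Slc40a1 rose 6.51-fold (log2 2.70 ± 0.37, adjusted p = 0.00741), Gstm1 4.82-fold (log2 2.27 ± 0.31, adjusted p = 0.00763) and the quinone reductase gene Nqo1 4.03-fold (log2 2.01 ± 0.27, adjusted p = 0.00741). The heme transporter gene Slc48a1 rose from 84.7 ± 5.74 to 211 ± 38.7 CPM (2.49-fold, adjusted p = 0.000634), and the ferritin genes Fth1 and Ftl1, which have pseudogenes that make their values uncertain, rose 2.14-fold (adjusted p = 0.000892) and 1.43-fold (adjusted p = 0.0384). Gclc rose 1.76-fold, the cystine transporter gene Slc7a11 2.11-fold and malic enzyme Me1 1.69-fold (adjusted p = 0.0104, 0.0322 and 0.00467). Outside these functions Foxd1 rose 8.05-fold, Ttn 6.19-fold, Daam2 4.44-fold and the lipoprotein lipase gene Lpl 2.51-fold, and the myosin light chain gene Myl9 1.78-fold (adjusted p = 0.0152, 0.00264, 0.00253, 0.0200 and 0.0154). The gene called lower without the block was Zdbf2, at 10.4 ± 3.65 CPM in mock and 3.03 ± 0.327 in T-N2G cells. Its log2 fold change was -1.78 ± 0.31 (adjusted p = 0.0355), a call lost without each of the 6 libraries in turn except mock vehicle replicate 1. The calls of Nqo1, Gstm1 and Slc40a1 were lost without mock vehicle replicate 3 (adjusted p = 0.0610, 0.0659 and 0.0610), and those of Foxd1, Ftl1, Gclc, Lpl, Myl9 and Slc7a11 without 3 or more of the 6 libraries in turn.

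In vehicle, edgeR called 38 genes higher and 1 lower in T-N2G cells of 12469 tested, 25 and 1 of them by at least 2-fold, and 800 genes had an unadjusted p under 0.05. With the block the counts were 381 and 404, and replicates 1 and 2 alone gave 5 and 1, or 182 and 113 with the block. Replicates 1 and 2 carry one series of library codes in the labels and replicate 3 another, a candidate batch. A test of group by series in edgeR was added after the data were seen, without and with replicate 1 against 2 as a further term. The series with replicate 3 has 1 library per group, so the test cannot decide whether effects differ between the series. Its counts of genes are therefore not given. For Thbs1 the log2 fold change of T-N2G over mock cells in DEM was -0.87, or -0.67 in replicates 1 and 2 alone. The number higher was 24, 18 and 14 without mock vehicle replicates 1, 2 and 3, and 21 and 20 without T-N2G vehicle replicates 1 and 3. The number lower was 3 without mock vehicle replicate 1 and 0 without each other library. By DESeq2 the counts were 80 and 25, and by limma on log2(FPKM + 1) 25 higher.

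Lists of genes were tested in the same comparison, with adjusted p given first for camera's preset correlation and then for an estimated one. Heme and iron handling had 4 of 16 members higher, 7 higher adjusted over the list alone and 7 higher with the block (adjusted p = 3.53e-17 and 0.000481). Glutathione synthesis and reduction had 2 of 10 members higher, 4 higher adjusted over the list alone and 4 higher with the block (adjusted p = 6.53e-09 and 0.0123, or 0.0550 for the estimated correlation with the block). The thioredoxin and peroxiredoxin system had 0 of 15 members called, 6 higher adjusted over the list alone and 7 higher and 1 lower with the block (adjusted p = 1.77e-07 and 0.0105, toward higher values, or 0.0629 for the estimated correlation with the block). The list of NADPH generation and pentose phosphate genes had 1 of 12 members higher, 5 higher adjusted over the list alone and 5 higher with the block (adjusted p = 1.61e-06 and 0.00742). CNC and small Maf factors had 2 of 11 members higher and 2 higher adjusted over the list alone (adjusted p = 1.09e-26 and 0.000315). The called members of the last were Nfe2l2 and Mafg themselves, so its test says nothing beyond their introduction, and the median log2 fold change of the list was -0.07 against a mean of 0.98. The camera calls of other lists were lost with an estimated correlation in the fit without the block. Glutathione S-transferases had 2 of 15 members higher, 5 higher adjusted over the list alone and 5 higher with the block (adjusted p = 1.03e-09 and 0.0560, or 0.00322 for the estimated correlation with the block). Quinone and carbonyl detoxification had 1 of 17 members higher, 5 higher and 1 lower adjusted over the list alone and 5 higher and 2 lower with the block (adjusted p = 0.000166 and 0.131). Other reported Nrf2 targets had 1 of 14 members higher, 3 higher adjusted over the list alone and 3 higher with the block (adjusted p = 0.000166 and 0.0532). Targets of p53 had 0 of 22 members called, 3 lower adjusted over the list alone and 9 lower with the block (adjusted p = 1.61e-06 and 0.308, toward lower values). Type I interferon response genes had 0 of 25 members called, 0 adjusted over the list alone and 6 lower with the block (adjusted p = 6.49e-05 and 0.729, toward lower values). Atf4 targets of the amino acid response had 0 of 30 members called, 0 adjusted over the list alone and 2 higher with the block (adjusted p = 0.00818 and 0.404, toward higher values). Actin cytoskeleton and TGF-beta or YAP response genes had 1 of 18 members higher, 2 higher adjusted over the list alone and 4 higher and 1 lower with the block (adjusted p = 0.00124 and 0.729). Bone and cartilage markers had 0 of 4 members called, 2 higher adjusted over the list alone and 2 higher with the block (adjusted p = 0.00351 and 0.132, toward higher values).

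The second comparison asked which genes differ between T-N2G and mock cells under DEM, where a difference again need not come from T-N2G. Gsta4 stood at 1.11 ± 0.273 CPM in mock and 177 ± 35.3 in T-N2G cells, 158-fold higher (log2 7.30 ± 0.35, n = 3, adjusted p = 1.62e-07). Slc40a1 was 67.9-fold higher (log2 6.09 ± 0.39), Gstm1 29.4-fold (log2 4.88 ± 0.32) and Nqo1 17.5-fold (log2 4.13 ± 0.26), with adjusted p = 2.16e-06, 2.30e-06 and 1.82e-06. Both subunit genes of glutamate-cysteine ligase, the first enzyme of glutathione synthesis, rose, Gclc 5.59-fold (adjusted p = 1.62e-07) and Gclm 5.51-fold (adjusted p = 1.62e-07), with Slc7a11 5.85-fold and the glutathione reductase gene Gsr 2.26-fold (adjusted p = 3.27e-06 and 5.62e-06). Sulfiredoxin Srxn1 rose 6.15-fold, Prdx6 5.90-fold and Prdx1 2.14-fold (adjusted p = 1.62e-07, 8.67e-06 and 2.30e-06). The pentose phosphate genes Pgd, Taldo1 and Tkt rose 5.88-, 2.41- and 1.69-fold (adjusted p = 1.62e-07, 1.57e-05 and 1.50e-05). Slc48a1 reached 633 ± 80.3 CPM, 7.36-fold above mock, and the drug efflux genes Abcc4 and Abcc1 were 3.36- and 2.77-fold higher (adjusted p = 1.62e-07, 1.62e-07 and 3.95e-05). Heph, which encodes a copper-dependent ferroxidase, was 72.4-fold higher, Pir 38.0-fold and Osgin1 10.4-fold, each from a mock level below 1 CPM (adjusted p = 0.000114, 7.22e-06 and 0.000139). Sstr5 and Gsta1 had 0 fragments in mock DEM and were at least 97.0-fold and 28.9-fold higher, with a floor of 3 counts over the group that covers counting error only. Members of the proliferin family, Prl2c2 (47.9-fold) and Prl2c3 (at least 210.2-fold, 0 rounded fragments in mock DEM), and Gm3776 (66.2-fold) also rose, but near-identical copies make their values uncertain.

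Genes that were lower in T-N2G cells under DEM included stress and immediate early genes. Atf3 stood at 6.39 ± 2.68 CPM in mock and 1.91 ± 0.0717 in T-N2G cells, 3.33-fold lower (log2 -1.73 ± 0.25, n = 3, adjusted p = 0.00141). Chac1 and Trib3 were 1.63- and 1.47-fold lower, Herpud1 1.37-fold, Hspb1 1.58-fold, Junb 1.54-fold, Klf4 1.74-fold and Dusp1 1.87-fold (adjusted p = 0.00955, 0.0346, 0.000949, 0.0107, 0.000528, 0.00518 and 0.0142). The near-identical heat shock genes Hspa1b and Hspa1a were 1.83- and 1.65-fold lower (adjusted p = 0.00485 and 0.0335). Other large falls by fold were those of Zdbf2 (4.26-fold), Cldn1 (4.09-fold), Dkk2 (3.39-fold), Angptl4 (3.09-fold) and the gap junction gene Gjb2 (2.94-fold), with adjusted p = 0.00235, 0.0192, 0.0192, 0.0495 and 0.00599. Matrix genes Thbs1, Col8a1 and Loxl3 were 1.83-, 1.42- and 1.55-fold lower, while Col4a1 was 1.24-fold higher (adjusted p = 0.00623, 0.000355, 0.00126 and 0.00704). The call of Hspb1 was lost without T-N2G DEM replicate 3 (adjusted p = 0.0550). The calls of Angptl4, Cldn1, Dkk2, Dusp1, Hspa1a and Trib3 were lost without 3 or more of the 6 libraries in turn.

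Under DEM, edgeR called 325 genes higher and 138 lower in T-N2G cells, 127 and 29 of them by at least 2-fold. With the block the counts were 1283 and 1162, and replicates 1 and 2 alone gave 117 and 22, or 866 and 715 with the block. Without mock DEM replicate 3 the count higher was 212, and the count lower was 63 without mock DEM replicate 3, 84 without T-N2G DEM replicate 1 and 86 without T-N2G DEM replicate 3. DESeq2 called 250 lower.

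The same lists were tested for T-N2G over mock cells under DEM. Heme and iron handling had 9 of 16 members higher and 10 higher adjusted over the list alone (adjusted p = 2.86e-48 and 1.14e-05). The thioredoxin and peroxiredoxin system had 7 of 15 members higher, 8 higher and 1 lower adjusted over the list alone and 9 higher and 1 lower with the block (adjusted p = 1.36e-31 and 7.03e-05). Glutathione synthesis and reduction had 4 of 10 members higher and 4 higher adjusted over the list alone (adjusted p = 8.70e-28 and 0.000372). The list of NADPH generation and pentose phosphate genes had 5 of 12 members higher and 5 higher adjusted over the list alone (adjusted p = 3.18e-25 and 6.28e-05). Quinone and carbonyl detoxification had 9 of 17 members higher and 1 lower and 11 higher and 1 lower adjusted over the list alone (adjusted p = 2.41e-23 and 0.00111, toward higher values), with Ces2g the gene that was lower (2.41-fold, adjusted p = 0.00858). Glutathione S-transferases had 7 of 15 members higher, 7 higher adjusted over the list alone and 7 higher and 1 lower with the block (adjusted p = 1.39e-12 and 0.0238). Drug efflux transporters had 2 of 5 members higher, 3 higher and 1 lower adjusted over the list alone and 3 higher and 1 lower with the block (adjusted p = 3.76e-10 and 0.00369). Other reported Nrf2 targets had 4 of 14 members higher and 6 higher adjusted over the list alone (adjusted p = 6.64e-11 and 0.00320, or 0.0516 for the estimated correlation with the block). CNC and small Maf factors had 3 of 11 members higher and 1 lower, 4 higher and 2 lower adjusted over the list alone and 4 higher and 3 lower with the block (adjusted p = 4.01e-11 and 0.00144, toward higher values), with Keap1 1.31-fold higher and Nfe2l1 1.16-fold lower. This list includes the introduced Nfe2l2 and Mafg, so its test says nothing of the other members. Immediate early genes had 4 of 21 members lower, 7 lower adjusted over the list alone and 1 higher and 10 lower with the block (adjusted p = 1.40e-06 and 0.0319, or 0.154 for the estimated correlation with the block).

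Other calls under DEM were lost with an estimated correlation in both fits. Atf4 targets of the amino acid response had 1 of 30 members higher and 3 lower, 1 higher and 7 lower adjusted over the list alone and 2 higher and 11 lower with the block (adjusted p = 0.00120 and 0.239, toward lower values), with Slc1a4 the gene that was higher (1.83-fold). Targets of p53 had 1 of 22 members higher and 3 lower, 1 higher and 4 lower adjusted over the list alone and 1 higher and 13 lower with the block (adjusted p = 0.000448 and 0.484, toward lower values), with Bax 1.27-fold higher and Pmaip1 1.60-fold lower. Proteasome subunits had 3 of 31 members higher, 7 higher adjusted over the list alone and 16 higher with the block (adjusted p = 0.000131 and 0.581). Unfolded protein response chaperones had 1 of 20 members lower, 3 lower adjusted over the list alone and 8 lower with the block (adjusted p = 0.000393 and 0.494). Collagens and extracellular matrix had 2 of 31 members higher and 3 lower, 3 higher and 11 lower adjusted over the list alone and 5 higher and 17 lower with the block (adjusted p = 0.000251 and 0.180, toward lower values). Autophagy and lysosome genes had 2 of 22 members higher, 2 higher adjusted over the list alone and 8 higher and 2 lower with the block (adjusted p = 0.0244 and 0.612). In this list Tfe3 was 1.60-fold and Sqstm1 1.74-fold higher (adjusted p = 5.07e-05 and 0.000612). Type I interferon response genes had 0 of 25 members called, 0 adjusted over the list alone and 1 higher and 5 lower with the block (adjusted p = 0.00455 and 0.672, toward lower values). Mitosis genes had 1 of 28 members higher, 2 higher adjusted over the list alone and 7 higher and 1 lower with the block (adjusted p = 0.0244 and 0.581). Fibroblast markers had 0 of 11 members called, 3 lower adjusted over the list alone and 6 lower with the block (adjusted p = 0.0244 and 0.494, toward lower values). The block added 1 call, which did not hold with an estimated correlation and the block. Matrix proteases and inhibitors had 1 of 18 members lower, 1 higher and 5 lower adjusted over the list alone and 5 higher and 8 lower with the block (adjusted p = 0.202 and 0.696, or 0.00360 toward lower values with the block). Adipocyte markers had 2 of 2 members higher and 2 higher adjusted over the list alone, Lpl at 4.91-fold and Pparg at 1.36-fold, with no set test. The calls of Bax, Nfe2l1 and Pparg were lost without 5 of the 6 libraries in turn.

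**Figure D2:**
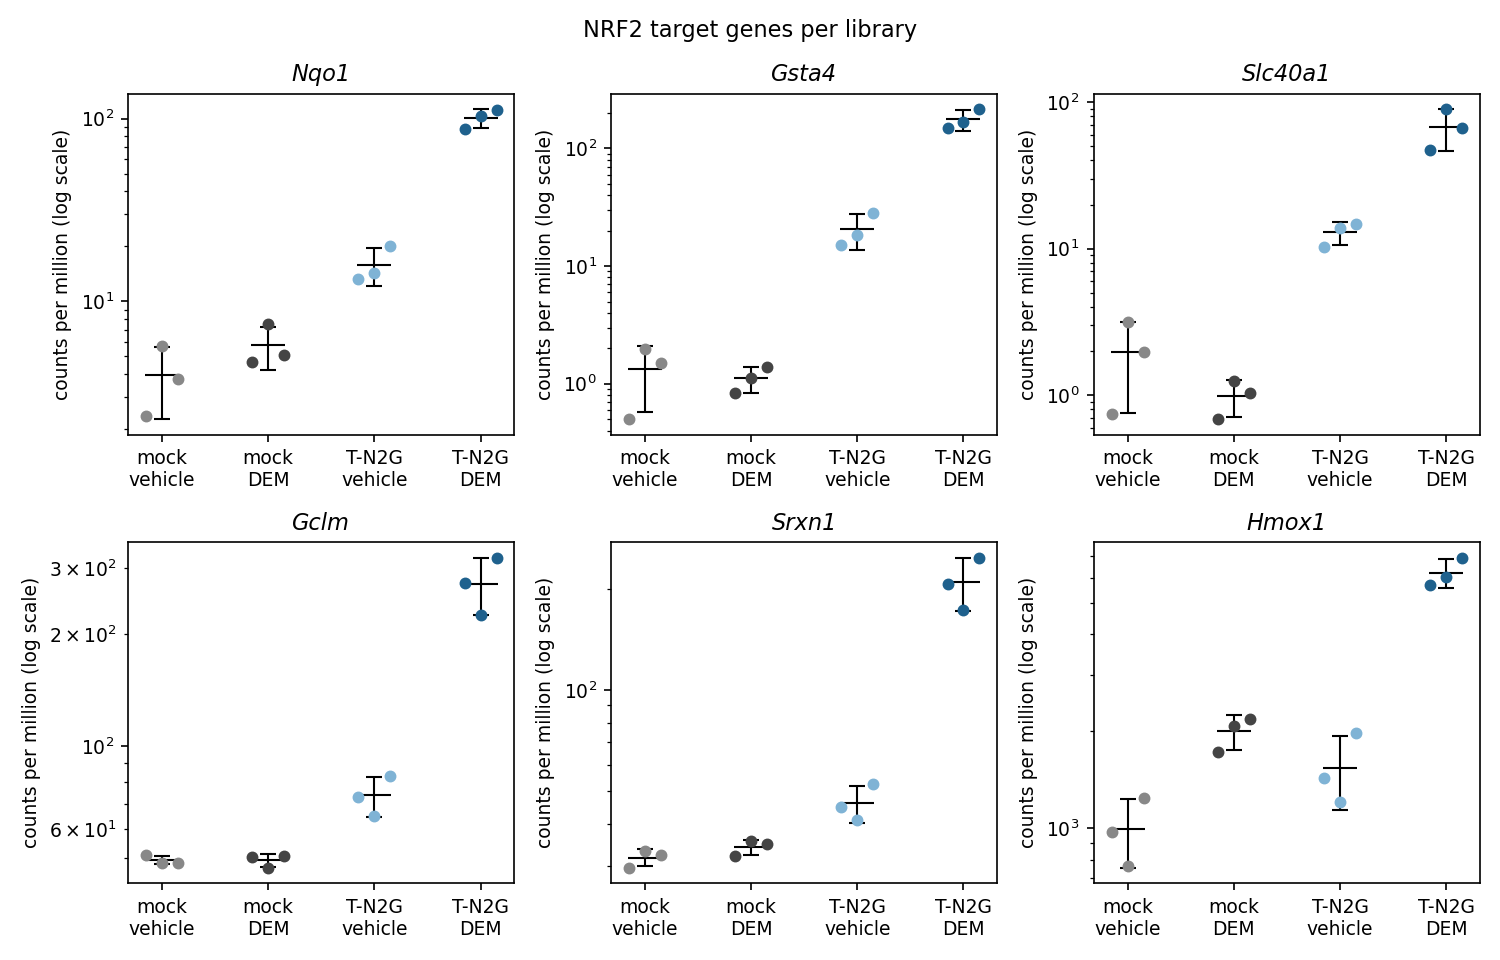
CPM (log axis) of Nqo1, Gsta4, Slc40a1, Gclm, Srxn1 and Hmox1 per library (points) with the group mean (bar) and SD in the 4 groups of 3 libraries. Mean Gsta4 was 1.33 and 1.11 CPM in mock cells without and with DEM, and 20.7 and 177 in T-N2G cells.

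The third comparison asked how cells without small Mafs respond to DEM. Genes called higher included targets of Atf4, a factor of the amino acid and integrated stress responses. Trib3 rose from 9.60 ± 0.154 to 29.2 ± 2.83 CPM, 3.04-fold (log2 1.60 ± 0.14, n = 3, adjusted p = 0.000155), Chac1 2.35-fold (log2 1.23 ± 0.14, adjusted p = 0.000598), Atf5 2.24-fold (log2 1.16 ± 0.10, adjusted p = 0.000155) and Ddit3 2.21-fold (log2 1.14 ± 0.15, adjusted p = 0.00118). Apobr rose 5.61-fold (log2 2.49 ± 0.15, adjusted p = 1.41e-05) and Angptl4 8.42-fold from 0.303 ± 0.0920 CPM (adjusted p = 0.00244). Heat shock gene Hspa1b rose 2.69-fold, the gene Herpud1 of ER-associated degradation 1.49-fold, Vegfa 1.99-fold and metallothionein Mt2 1.65-fold (adjusted p = 0.000567, 0.000598, 0.00171 and 0.0224). Of the p53 targets that were called, Plk2 fell by 1.72-fold, Perp by 1.56-fold and Bax by 1.38-fold (adjusted p = 0.00118, 0.00654 and 0.00362), and so did Vcam1 (1.68-fold, adjusted p = 0.00174) and Bach2 (1.58-fold, adjusted p = 0.00512). Other large falls were of Ptprv (3.80-fold), Smarca1 (3.18-fold), Tro (3.01-fold), Npr3 (2.94-fold) and Lrch2 (2.92-fold), beside Gm21992 (18.0-fold), whose value is uncertain because it overlaps Rbm14 and Rbm4 in the reference annotation GRCm38.p6. The call of Smarca1 was lost without mock DEM replicate 1 (adjusted p = 0.0520), those of Mt2 and Ptprv without 3 or more of the 6 libraries in turn, and that of Gm21992 without each. Among Nrf2 target genes, Hmox1 rose from 997 ± 241 to 2000.0 ± 246 CPM (2.01-fold, adjusted p = 0.00753), Gss 1.43-fold (adjusted p = 0.00155) and Slc7a11 1.60-fold (adjusted p = 0.0328, lost without each of the 6 libraries in turn). Other genes of the lists pooled below fell, among them Abcb6 (log2 -0.54 ± 0.11, adjusted p = 0.00746) and Tkt (log2 -0.25 ± 0.06, adjusted p = 0.0228). The call of Tkt was lost under 6 of 20 alternatives (adjusted p up to 0.205). The 103 tested genes of the 8 Nrf2 target lists had a median log2 fold change of -0.13. Nqo1 had a log2 fold change of 0.54 ± 0.29 (adjusted p = 0.235, or 0.0446 with the block and 0.0446 to 0.561 over all alternatives), Gclm 0.00 ± 0.12 (adjusted p = 0.996), Srxn1 0.10 ± 0.13 (adjusted p = 0.629) and Gsta4 -0.26 ± 0.50 (adjusted p = 0.766).

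DEM in mock cells was followed by 967 genes called higher and 770 lower, 27 and 81 of them by at least 2-fold. With the block the counts were 2603 and 2736. Replicates 1 and 2 alone gave 57 and 67, or 2139 and 2223 with the block. The count higher was 521, 541 and 591 without mock DEM replicates 1, 2 and 3, and 577 and 524 without mock vehicle replicates 1 and 3. The count lower was 399, 380 and 418 without mock DEM replicates 1, 2 and 3, and 488 and 450 without mock vehicle replicates 2 and 3. With only these 6 libraries in the fit 617 were higher.

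No camera call of a gene list in mock cells held with an estimated correlation. Atf4 targets of the amino acid response had 17 of 30 members higher, 19 higher adjusted over the list alone and 21 higher and 2 lower with the block (adjusted p = 2.74e-14 and 0.0682). Unfolded protein response chaperones had 9 of 20 members higher, 15 higher adjusted over the list alone and 18 higher with the block (adjusted p = 4.12e-09 and 0.374). Heat shock response genes had 5 of 16 members higher, 7 higher adjusted over the list alone and 10 higher with the block (adjusted p = 0.000150 and 0.374). Autophagy and lysosome genes had 3 of 22 members higher, 3 higher adjusted over the list alone and 11 higher with the block (adjusted p = 0.0192 and 0.573). Targets of p53 had 10 of 22 members lower, 13 lower adjusted over the list alone and 20 lower with the block (adjusted p = 1.31e-08 and 0.374). Cytosolic ribosomal proteins had 4 of 40 members lower, 3 lower adjusted over the list alone and 1 higher and 31 lower with the block (adjusted p = 1.59e-05 and 0.573). Respiratory chain subunits had 5 of 30 members lower, 11 lower adjusted over the list alone and 15 lower with the block (adjusted p = 0.000150 and 0.374). Proteasome subunits had 5 of 31 members lower, 5 lower adjusted over the list alone and 1 higher and 19 lower with the block (adjusted p = 0.00171 and 0.573). DNA replication genes had 4 of 29 members lower, 4 lower adjusted over the list alone and 17 lower with the block (adjusted p = 0.0101 and 0.573). Inflammatory cytokines and NF-kB targets had 3 of 17 members lower, 5 lower adjusted over the list alone and 1 higher and 9 lower with the block (adjusted p = 0.00884 and 0.374). Quinone and carbonyl detoxification had 2 of 17 members lower, 6 lower adjusted over the list alone and 1 higher and 10 lower with the block (adjusted p = 0.00488 and 0.374). The list of NADPH generation and pentose phosphate genes had 2 of 12 members lower, 4 lower adjusted over the list alone and 7 lower with the block (adjusted p = 0.0245 and 0.374). Type I interferon response genes had 1 of 25 members lower, 1 lower adjusted over the list alone and 16 lower with the block (adjusted p = 0.00983 and 0.612). The called members of the quinone and interferon lists were Akr1b10, Aldh1a1 and Ifit2, each lost without 2 or more of the 6 libraries in turn. The block added 2 calls. Cholesterol synthesis and uptake had 0 of 23 members called, 0 adjusted over the list alone and 15 lower with the block (adjusted p = 0.101 and 0.800, or 0.000262 toward lower values with the block). Collagens and extracellular matrix had 2 of 31 members higher and 2 lower, 2 higher and 2 lower adjusted over the list alone and 4 higher and 15 lower with the block (adjusted p = 0.155 and 0.573, or 0.00704 toward lower values with the block). Metallothionein and zinc response genes had 3 of 4 members higher and 1 lower and 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.283 and 0.573), the member lower being the zinc importer gene Slc39a10 (1.63-fold, adjusted p = 0.00178).

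The fourth comparison asked how T-N2G cells respond to DEM. Genes called higher included known Nrf2 targets. Nqo1 rose from 15.9 ± 3.75 to 101 ± 12.2 CPM, 6.32-fold (log2 2.66 ± 0.23, n = 3, adjusted p = 4.70e-05), Gsta4 8.56-fold (log2 3.10 ± 0.26, adjusted p = 2.82e-05), Slc40a1 5.27-fold (log2 2.40 ± 0.29, adjusted p = 0.000371) and Srxn1 4.55-fold (log2 2.19 ± 0.13, adjusted p = 5.30e-06). Hmox1 rose 4.03-fold to 6212 ± 643 CPM (adjusted p = 0.000110). Slc7a11 rose 4.43-fold, Gclm 3.70-fold, Gclc 3.62-fold, Pgd 3.25-fold, Slc48a1 3.00-fold and Abcc4 2.77-fold (adjusted p = 2.10e-05, 5.56e-06, 5.56e-06, 1.07e-05, 1.75e-05 and 5.30e-06). Catalase Cat rose 2.00-fold, G6pdx 1.74-fold, Keap1, whose protein holds Nrf2 in the cytoplasm, 1.41-fold, Mt1 2.02-fold and Tfe3 1.88-fold (adjusted p = 9.42e-05, 0.00103, 0.000740, 0.000709 and 1.07e-05). Sstr5 rose 9.07-fold (adjusted p = 0.00198), and Prl2c2, Prl2c4 and Prl2c3, with the uncertainty of their family, 9.70-, 14.0- and 6.93-fold. Genes called lower included members of the matrix, p53 and NF-kB lists. Thbs1 fell by 2.22-fold, Timp3 by 2.35-fold, Fbn1 by 1.80-fold, Plk2 by 2.11-fold, Tnfaip3 by 3.21-fold, Klf4 by 2.01-fold and Bach2 by 1.91-fold (adjusted p = 0.000674, 0.00978, 0.00234, 6.60e-05, 0.00186, 0.000710 and 0.000482). Among the genes that passed the naming rule the largest falls by fold were of Ptprv (4.97-fold), Npr3 (3.93-fold), Cd80 (3.86-fold) and Samd5 (3.84-fold).

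In T-N2G cells edgeR called 1254 genes higher and 941 lower under DEM, 80 and 138 of them by at least 2-fold. With the block the counts were 2846 and 2769. Replicates 1 and 2 alone gave 305 and 174, or 2382 and 2258 with the block. Without T-N2G DEM replicate 3 and without T-N2G vehicle replicate 1 the counts higher were 827 and 756. The counts lower were 594, 604 and 568 without T-N2G DEM replicate 1, T-N2G DEM replicate 3 and T-N2G vehicle replicate 1. With only these 6 libraries in the fit the counts were 746 and 596.

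Among the lists in T-N2G cells, glutathione synthesis and reduction had 6 of 10 members higher and 1 lower, 7 higher and 1 lower adjusted over the list alone and 7 higher and 2 lower with the block (adjusted p = 5.10e-14 and 0.00781, toward higher values), with Gpx1 lower (1.35-fold). Heme and iron handling had 9 of 16 members higher and 9 higher adjusted over the list alone (adjusted p = 5.41e-12 and 0.00377). The list of NADPH generation and pentose phosphate genes had 5 of 12 members higher, 5 higher and 1 lower adjusted over the list alone and 6 higher and 2 lower with the block (adjusted p = 0.000488 and 0.0287). The thioredoxin and peroxiredoxin system had 8 of 15 members higher and 2 lower and 8 higher and 2 lower adjusted over the list alone (adjusted p = 1.44e-07 and 0.0121, toward higher values), with Txnip among the lower (1.67-fold). Other reported Nrf2 targets had 6 of 14 members higher and 1 lower, 7 higher and 2 lower adjusted over the list alone and 7 higher and 3 lower with the block (adjusted p = 4.29e-06 and 0.0287, toward higher values, or 0.129 for the estimated correlation with the block), with Ufsp2 lower. The camera calls of further lists were lost with an estimated correlation in the fit without the block. Quinone and carbonyl detoxification had 7 of 17 members higher and 3 lower and 8 higher and 4 lower adjusted over the list alone (adjusted p = 0.000902 and 0.173, toward higher values), with Akr1b8 among the lower (1.68-fold). Glutathione S-transferases had 6 of 15 members higher, 6 higher adjusted over the list alone and 6 higher and 3 lower with the block (adjusted p = 0.00414 and 0.338, or 0.0367 for the estimated correlation with the block). Drug efflux transporters had 2 of 5 members higher and 1 lower and 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.000488 and 0.0986, toward higher values), with Abcg2 lower (1.33-fold). Autophagy and lysosome genes had 7 of 22 members higher, 8 higher adjusted over the list alone and 15 higher and 1 lower with the block (adjusted p = 6.49e-06 and 0.264, or 0.0339 for the estimated correlation with the block). Atf4 targets of the amino acid response had 6 of 30 members higher and 1 lower, 9 higher and 2 lower adjusted over the list alone and 13 higher and 7 lower with the block (adjusted p = 0.00590 and 0.296, toward higher values). Unfolded protein response chaperones had 4 of 20 members higher, 4 higher adjusted over the list alone and 14 higher with the block (adjusted p = 0.00231 and 0.496).

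Lower values under DEM in T-N2G cells were called in more lists and lost with an estimated correlation in the fit without the block. Targets of p53 had 12 of 22 members lower, 15 lower adjusted over the list alone and 19 lower with the block (adjusted p = 4.63e-08 and 0.188). Inflammatory cytokines and NF-kB targets had 5 of 17 members lower, 7 lower adjusted over the list alone and 1 higher and 9 lower with the block (adjusted p = 0.000995 and 0.177, or 0.0485 for the estimated correlation with the block). Cytosolic ribosomal proteins had 11 of 40 members lower, 13 lower adjusted over the list alone and 34 lower with the block (adjusted p = 1.45e-06 and 0.372). Respiratory chain subunits had 4 of 30 members lower, 4 lower adjusted over the list alone and 16 lower with the block (adjusted p = 0.000792 and 0.296). Collagens and extracellular matrix had 2 of 31 members higher and 8 lower, 2 higher and 9 lower adjusted over the list alone and 2 higher and 21 lower with the block (adjusted p = 3.54e-05 and 0.155, toward lower values, or 0.0339 for the estimated correlation with the block), with Col4a1 1.21-fold higher. Bone and cartilage markers had 2 of 4 members lower, 3 lower adjusted over the list alone and 4 lower with the block (adjusted p = 0.00310 and 0.155). Type I interferon response genes had 3 of 25 members lower, 3 lower adjusted over the list alone and 13 lower with the block (adjusted p = 0.00590 and 0.613). DNA replication genes had 5 of 29 members lower, 5 lower adjusted over the list alone and 2 higher and 14 lower with the block (adjusted p = 0.0403 and 0.590). The block added 6 calls, none of which held with an estimated correlation and the block. Matrix proteases and inhibitors had 4 of 18 members lower, 4 lower adjusted over the list alone and 3 higher and 8 lower with the block (adjusted p = 0.0826 and 0.578, or 0.000965 toward lower values with the block). Actin cytoskeleton and TGF-beta or YAP response genes had 3 of 18 members lower, 3 lower adjusted over the list alone and 1 higher and 8 lower with the block (adjusted p = 0.0530 and 0.664, or 0.000845 toward lower values with the block). Cholesterol synthesis and uptake had 0 of 23 members called, 0 adjusted over the list alone and 13 lower with the block (adjusted p = 0.221 and 0.846, or 0.0111 toward lower values with the block). Fibroblast markers had 0 of 11 members called, 0 adjusted over the list alone and 2 higher and 7 lower with the block (adjusted p = 0.161 and 0.611, or 0.0324 toward lower values with the block). Heat shock response genes had 4 of 16 members higher and 4 higher adjusted over the list alone (adjusted p = 0.0628 and 0.504, or 0.0411 toward higher values with the block). Metallothionein and zinc response genes had 3 of 4 members higher and 1 lower and 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0889 and 0.266, or 0.0140 toward higher values with the block). The calls of Akr1b8, Prl2c4, Ptprv and Ufsp2 were lost without 2 or more of the 6 libraries in turn.

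The fifth comparison tested whether the response to DEM differs between T-N2G and mock cells, as the difference of their log2 fold changes. The genes with a positive difference included members of the glutathione, NADPH, heme and iron lists. Srxn1 went from 31.7 ± 1.88 to 34.1 ± 1.83 CPM under DEM in mock cells and from 46.0 ± 5.88 to 209 ± 37.6 in T-N2G cells, a difference of 2.08 ± 0.18 (log2, n = 3, adjusted p = 0.000282). The differences were 1.91 ± 0.17 for Pgd, 1.88 ± 0.17 for Gclm, 1.67 ± 0.16 for Gclc, 1.42 ± 0.12 for Abcc4, 1.56 ± 0.17 for Slc48a1 and 1.36 ± 0.15 for Abcb6 (adjusted p = 0.000302, 0.000302, 0.000529, 0.000282, 0.00164 and 0.00121). Gsr, catalase, Me1, Prdx1 and Sod1 differed by 0.94 ± 0.12, 1.03 ± 0.14, 1.02 ± 0.14, 0.76 ± 0.10 and 0.65 ± 0.09 (adjusted p = 0.00516, 0.00649, 0.00649, 0.00649 and 0.00649), and the ferritin genes Fth1 and Ftl1 by 1.11 ± 0.16 and 0.95 ± 0.13 (adjusted p = 0.00901 and 0.00649). Larger differences with larger errors were those of Pir (3.41 ± 0.61), Slc40a1 (3.38 ± 0.57), Gsta4 (3.36 ± 0.57), Gstm1 (2.61 ± 0.45) and Nqo1 (2.12 ± 0.37), with adjusted p = 0.0311, 0.0258, 0.0258, 0.0258 and 0.0311, and these 5 calls were each lost without 7 or more of the 12 libraries in turn. Called with a negative difference without the block was Spry1 (-0.69 ± 0.10, adjusted p = 0.00903), which went from 49.3 to 30.1 CPM in T-N2G cells and from 52.7 to 51.8 in mock cells. The other was Herpud1 (-0.47 ± 0.09, adjusted p = 0.0426), whose call was lost without 11 of the 12 libraries in turn. Hmox1 had a difference of 1.01 ± 0.28 with an adjusted p of 0.348, or 0.000196 with the block (0.000196 to 0.860 over all alternatives).

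**Figure D3:**
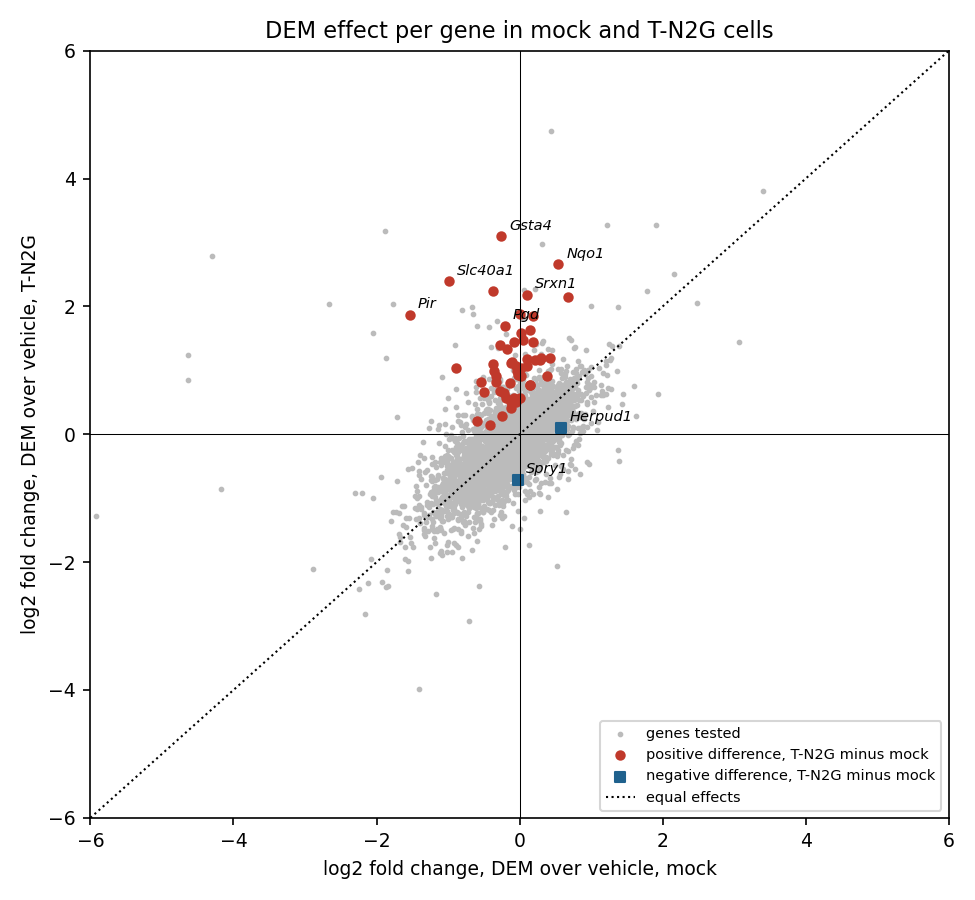
Log2 fold change of each tested gene under DEM in mock cells (x axis) and in T-N2G cells (y axis), with the 52 genes of positive difference (T-N2G minus mock) as red points, the 2 of negative difference as blue squares, and equal effects as a dotted line. Srxn1 sat at 0.10 and 2.19, and 1 gene lay outside the axes.

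The difference, T-N2G minus mock, was called positive for 52 genes and negative for 2, 30 of the 52 by at least 2-fold, and 455 genes had an unadjusted p under 0.05. With the block the counts were 227 and 122, and by DESeq2 82 and 14. Replicates 1 and 2 alone gave 6 positive and 0 negative, or 133 and 62 with the block. The count of positive differences was 22, 34 and 27 without mock DEM replicates 1, 2 and 3, 29 and 34 without mock vehicle replicates 2 and 3, 33 and 31 without T-N2G DEM replicates 1 and 3, and 29, 28 and 33 without T-N2G vehicle replicates 1, 2 and 3. The count of negative differences was 1 without mock DEM replicate 1 or 3, mock vehicle replicate 1 or 2, T-N2G DEM replicate 1 or 3, and T-N2G vehicle replicate 1 or 2.

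Lists tested for the difference are given in the same way, with higher and lower standing for a positive and a negative difference, whatever the direction of the effects themselves. Heme and iron handling had 5 of 16 members higher, 8 higher adjusted over the list alone and 8 higher with the block (adjusted p = 3.68e-40 and 3.18e-05). The thioredoxin and peroxiredoxin system had 6 of 15 members higher, 7 higher adjusted over the list alone and 7 higher and 1 lower with the block (adjusted p = 1.58e-30 and 6.92e-05). Glutathione synthesis and reduction had 4 of 10 members higher and 4 higher adjusted over the list alone (adjusted p = 1.07e-23 and 0.000601). The list of NADPH generation and pentose phosphate genes had 5 of 12 members higher and 5 higher adjusted over the list alone (adjusted p = 1.07e-23 and 6.92e-05). Quinone and carbonyl detoxification had 3 of 17 members higher, 8 higher adjusted over the list alone and 9 higher with the block (adjusted p = 2.02e-24 and 0.000964). Drug efflux transporters had 2 of 5 members higher and 2 higher adjusted over the list alone (adjusted p = 2.10e-15 and 0.00103). Other reported Nrf2 targets had 2 of 14 members higher and 4 higher adjusted over the list alone (adjusted p = 6.47e-07 and 0.0141, or 0.0742 for the estimated correlation with the block). Atf4 targets of the amino acid response had 1 of 30 members higher, 1 higher and 3 lower adjusted over the list alone and 1 higher and 8 lower with the block (adjusted p = 7.01e-12 and 0.0165, toward lower values, or 0.0742 for the estimated correlation with the block), the gene with the positive difference being Slc1a4 (0.77 ± 0.11, adjusted p = 0.0110). Immediate early genes had 0 of 21 members called, 1 lower adjusted over the list alone and 4 lower with the block (adjusted p = 7.33e-08 and 0.0193, toward lower values, or 0.0863 for the estimated correlation with the block). The camera calls of other lists for the difference were lost with an estimated correlation in the fit without the block. Glutathione S-transferases had 2 of 15 members higher and 2 higher adjusted over the list alone (adjusted p = 6.30e-05 and 0.191, or 0.0488 for the estimated correlation with the block). Unfolded protein response chaperones had 1 of 20 members lower and 1 lower adjusted over the list alone (adjusted p = 0.000216 and 0.475). Autophagy and lysosome genes had 1 of 22 members higher, 2 higher adjusted over the list alone and 3 higher with the block (adjusted p = 0.000185 and 0.406, or 0.0279 for the estimated correlation with the block). This gene was Tfe3 (0.52 ± 0.09, adjusted p = 0.0311), whose call was lost without 10 of the 12 libraries in turn. Proteasome subunits had 0 of 31 members called, 0 adjusted over the list alone and 4 higher with the block (adjusted p = 0.000219 and 0.586, toward higher values). Mitosis genes had 0 of 28 members called and 0 adjusted over the list alone (adjusted p = 0.00559 and 0.475, toward higher values). Heat shock response genes had 0 of 16 members called, 3 lower adjusted over the list alone and 3 lower with the block (adjusted p = 0.00730 and 0.416, toward lower values). Collagens and extracellular matrix had 0 of 31 members called, 0 adjusted over the list alone and 9 lower with the block (adjusted p = 5.24e-06 and 0.0815, toward lower values, or 0.0115 for the estimated correlation with the block). Actin cytoskeleton and TGF-beta or YAP response genes had 0 of 18 members called, 0 adjusted over the list alone and 3 lower with the block (adjusted p = 0.00159 and 0.576, toward lower values). Bone and cartilage markers had 0 of 4 members called, 1 lower adjusted over the list alone and 1 lower with the block (adjusted p = 0.000735 and 0.0757, toward lower values).

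The block added 3 calls for the difference, none of which held with an estimated correlation and the block. Matrix proteases and inhibitors had 0 of 18 members called, 0 adjusted over the list alone and 3 lower with the block (adjusted p = 0.122 and 0.619, or 0.00125 toward lower values with the block). Fatty acid synthesis and desaturation had 0 of 16 members called, 0 adjusted over the list alone and 2 higher with the block (adjusted p = 0.244 and 0.814, or 0.0109 toward higher values with the block). Fibroblast markers had 0 of 11 members called and 0 adjusted over the list alone (adjusted p = 0.0550 and 0.552, or 0.00553 toward lower values with the block).

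Fold changes were compared across the 12469 genes, which are not independent replicates. The T-N2G effect in vehicle and that in DEM, which share no library, had a Pearson r of 0.694 and a Spearman rho of 0.530. Of the 38 genes higher in vehicle 37 were higher in DEM, where independent lists would share 0.990. The 37 include the introduced Nfe2l2 and Mafg. Both comparisons use the same mock and T-N2G populations, and replicate numbers pair their libraries. Other differences between the populations would therefore be shared too, and the overlap does not show an effect of T-N2G. Zdbf2 was lower in both. With the block 281 of the 381 genes higher in vehicle were higher in DEM, against 39.2 for independent lists. Of the 404 genes lower in vehicle 312 were lower in DEM, against 37.6. Another 6 were higher in vehicle and lower in DEM, and 3 the reverse. The DEM effects in mock and T-N2G cells had a Pearson r of 0.642 and a Spearman rho of 0.757, with 696 genes higher in both against 97.3 for independent lists and 536 lower in both against 58.1. Without the block Abcb6, Cgnl1, Cyb5a, Pik3ap1 and Tkt were called lower under DEM in mock cells and higher in T-N2G cells, and 0 genes the reverse. With the block these counts were 46 and 15. The call of Tkt in mock cells was lost under 6 of 20 alternatives. Called higher in both with the block were 1936 genes against 594 for independent lists, and lower in both 1976 against 608.

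The remaining lists had few calls. With an estimated correlation the camera calls that held both without and with the block were heme and iron handling and NADPH generation in every comparison but DEM in mock cells, glutathione synthesis and reduction and the thioredoxin system for T-N2G over mock cells in DEM, for DEM in T-N2G cells and for the difference, quinone detoxification and drug efflux for T-N2G over mock cells in DEM and for the difference, and glutathione S-transferases for T-N2G over mock cells in DEM. The CNC and small Maf list is left out of this count. Each other call with an estimated correlation depended on the block. For DEM in T-N2G cells glycolysis and hypoxia response genes had 3 of 22 members higher and 1 lower, 3 higher and 1 lower adjusted over the list alone and 6 higher and 4 lower with the block (adjusted p = 0.341 and 0.727), with Ndrg1 lower (1.65-fold, adjusted p = 0.00110). For DEM in mock cells neural markers had 1 of 5 members lower, 1 lower adjusted over the list alone and 1 higher and 2 lower with the block (adjusted p = 0.379 and 0.573), the gene being Stmn2 (1.62-fold, adjusted p = 0.00612). For DEM in T-N2G cells epithelial markers had 0 of 3 members called, 0 adjusted over the list alone and 1 higher and 2 lower with the block (adjusted p = 0.422 and 0.664). Skeletal and cardiac muscle markers had 0 of 4 members called, 0 adjusted over the list alone and 1 lower with the block (adjusted p = 0.724 and 0.846). Lists with fewer than 3 members tested had no set test. Macrophage markers had 0 of 2 members called, 1 lower adjusted over the list alone and 1 lower with the block for T-N2G over mock cells in DEM. For DEM in T-N2G cells endothelial markers had 0 of 2 members called, 1 lower adjusted over the list alone and 2 lower with the block, and replication-dependent histones had 0 of 2 members called, 1 higher adjusted over the list alone and 1 higher with the block. The most abundant members of these marker lists were Cd14 at 4.94 CPM and Kdr at 8.84 CPM in mock vehicle, against Vim of the fibroblast list at 2791. The glutathione S-transferase median under DEM in mock cells was -0.13, or -0.06 with Gsta1 at its bound. List median, mean and camera direction differed in sign for the CNC list, inflammatory genes, matrix proteases, neural and muscle markers for T-N2G in vehicle, for inflammatory genes, matrix proteases, the actin list, glycolysis and bone markers for T-N2G in DEM, for efflux transporters, other Nrf2 targets, the actin list and muscle markers for DEM in mock cells, for the CNC list and mitosis for DEM in T-N2G cells, and for interferon, epithelial and neural lists for the difference.

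**Figure D4:**
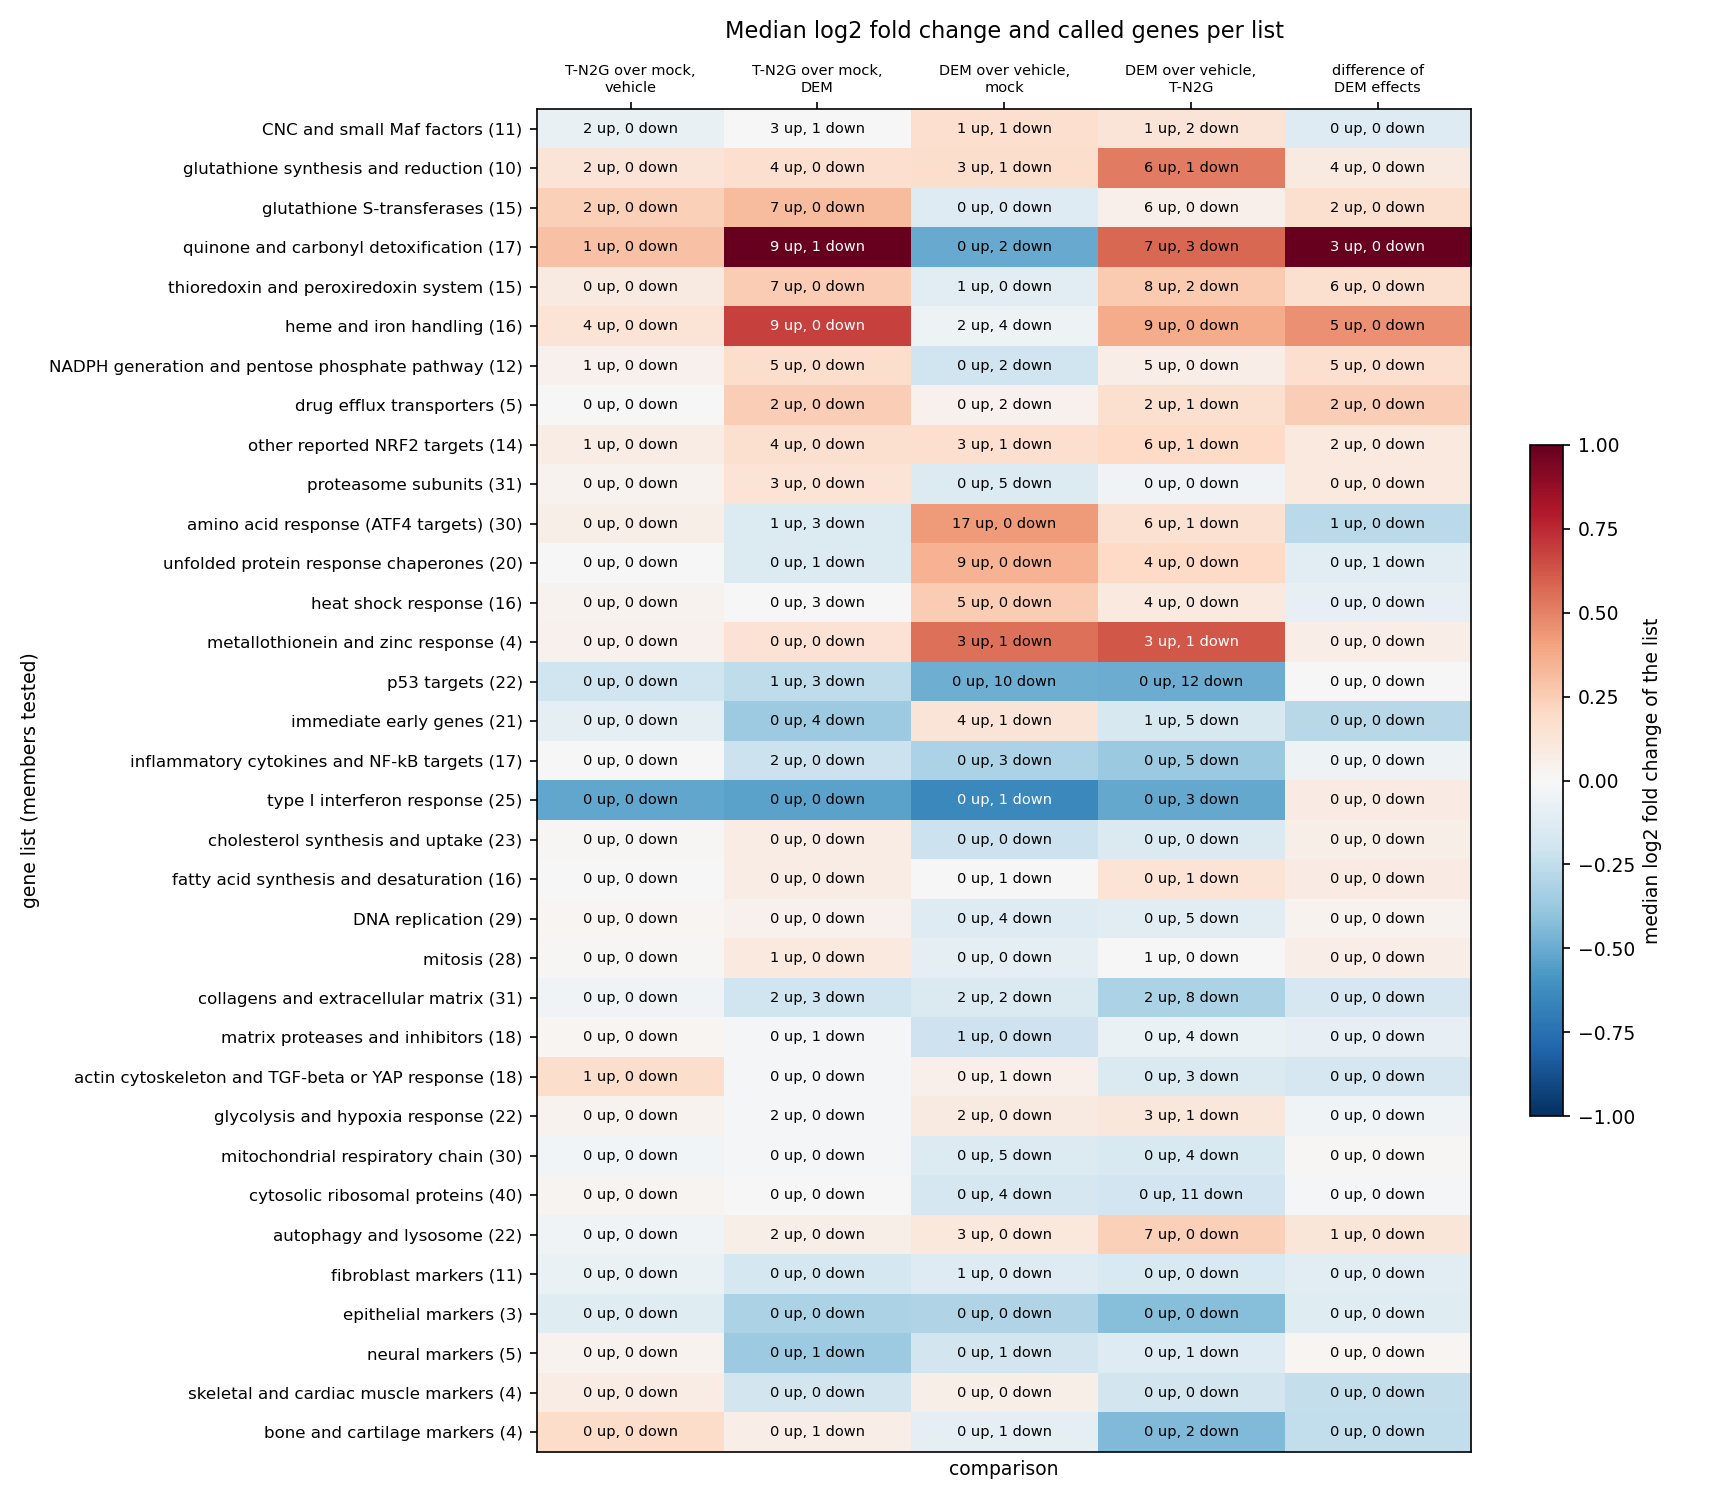
Median log2 fold change (colour, limited to -1 and 1) and number of called genes up and down in each list with at least 3 tested members (vertical axis, number tested in brackets) in the 5 comparisons (horizontal axis). Heme and iron handling had 9 of 16 members up for T-N2G over mock cells in DEM.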

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

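The test on transgene RNA was chosen after the result it measures was seen, and the tests on depth, on the level of expression and on other splits before. The difference between the DEM effects in T-N2G and mock cells was tested gene by gene, and as T-N2G minus mock it was called positive for 52 genes, negative for 2, and in either direction for 18 gene lists. With the replicate block it was called positive for 227 genes and negative for 122, and every call below was kept. A negative difference is not always a smaller effect, since Spry1 fell in T-N2G cells (log2 -0.71) and had -0.02 in mock cells. Among the named genes the log2 differences for glutathione synthesis, transport and conjugation were 1.88 for Gclm, 1.67 for Gclc, 0.94 for Gsr, 1.47 for Slc7a11, 3.36 for Gsta4 and 2.61 for Gstm1. Those for quinone and carbonyl metabolism were 2.12 for Nqo1, 1.35 for Ptgr1 and 1.52 for Esd, and those for redox enzymes 2.08 for Srxn1, 0.76 for Prdx1, 0.65 for Sod1 and 1.03 for Cat. Heme and iron genes differed by 3.38 for Slc40a1, 1.36 for Abcb6, 1.56 for Slc48a1, 0.95 for Ftl1 and 1.11 for Fth1. NADPH genes differed by 1.91 for Pgd, 1.02 for Me1, 0.54 for Tkt and 0.86 for Taldo1, and efflux genes by 1.42 for Abcc4 and 1.08 for Abcc1. The others were 3.41 for Pir, 1.92 for Pik3ap1, 0.77 for Slc1a4 and 0.52 for Tfe3, and -0.69 for Spry1 and -0.47 for Herpud1. The calls of Gsta4, Gstm1, Nqo1, Slc40a1, Tkt, Taldo1, Abcc1, Slc7a11, Pir, Pik3ap1, Tfe3 and Herpud1 were each lost in the fit without the block when 7 or more of the 12 libraries were left out in turn, and those of Esd and Ptgr1 without mock DEM replicate 1.

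More transgene RNA under DEM would raise Nfe2l2 and Mafg, whose fragments in T-N2G cells include the transgene's, by a log2 fold change of at least 0.5, but Nfe2l2 had -0.11 (SE 0.14) and Mafg -0.18 (SE 0.15), and the values plus 2 SE were 0.18 and 0.12. Thinning all libraries to the lowest total gave 56 called genes in place of 54, with 53 in both, which argues against unequal depth. The 8 lists pooled here are those pooled for DEM in mock cells, and their members need not all be Nrf2 targets. Their 103 tested genes had a median difference of 0.27 with 83 positive. This was above 100% of 10000 random lists matched on level (highest median 0.05), which argues against a shift tied to the level of expression. The median DEM effect of the 103 genes was -0.13 in mock and 0.21 in T-N2G cells. A candidate explanation that stays open is that DEM acts on the T-N2G protein, which was not measured, and other differences between the cell populations besides T-N2G may contribute.

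The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, and for the difference the 6 pairs of vehicle and DEM libraries likewise, too few for a share under 0.05. In each of the 5 comparisons 1 of the 10 splits, the real one, reached the real number of called genes. The real numbers were 39 for T-N2G over mock cells in vehicle, 463 in DEM, 1737 for DEM in mock cells, 2195 in T-N2G cells and 54 for the difference, and the highest of any other split was 0. The 4 splits that part all pairs and the 6 that part 1 pair did not differ in this, since each but the real one gave 0. Every other split mixes libraries of both kinds, so the real effects widen the spread within groups and few calls can follow. The splits therefore cannot decide whether the real numbers arose by chance.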

How the results depend on the processing

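The alternatives added after the data were seen were the block with replicates 1 and 2 alone, the estimated correlation with the block, the test of group by series, and, for the agreement of the effects, leaving out a replicate number and all alternatives of the DEM effect. Counts are given as higher and lower, and the cause of a change was not tested unless stated. With the replicate block the counts were 381 and 404 for T-N2G over mock cells in vehicle (38 and 1 without it), 1283 and 1162 in DEM (325 and 138), 2603 and 2736 for DEM in mock cells (967 and 770), 2846 and 2769 in T-N2G cells (1254 and 941) and 227 and 122 for the difference (52 and 2). At least 2-fold they were 54 and 28, 170 and 85, 36 and 175, 99 and 231, and 52 and 3 in that order. The block keeps the spread between replicate numbers out of the residual, whose coefficient of variation fell from 0.110 to 0.0428. All 39, 463, 1737, 2195 and 54 genes called without the block were called with it in the same direction. Of the named genes and the camera tests of lists the block changed no call besides those given with both values in the report, 16 of them at an estimated correlation, and among the genes chosen after their values were seen it added calls of Eif2s3y and of imprinted genes. Replicates 1 and 2 alone, with fewer samples, gave 5 and 1, 117 and 22, 57 and 67, 305 and 174, and 6 and 0 in the same order, or 182 and 113, 866 and 715, 2139 and 2223, 2382 and 2258, and 133 and 62 with the block.

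DESeq2 called 80 and 25 for T-N2G in vehicle, 250 lower in DEM, and 82 and 14 for the difference. For T-N2G in vehicle limma called 25 higher on log2(FPKM + 1) and 21 and 0 on genes at 1 FPKM in 3 libraries. With only the groups compared in the fit, and so fewer samples, the counts were 16 and 0 for T-N2G in vehicle, 617 higher for DEM in mock cells, and 746 and 596 in T-N2G cells. Scaling by library size alone called 2 lower for T-N2G in vehicle and 1 negative for the difference, and no filter 3 lower and 1 negative. Neither RLE scaling nor library size alone moved the share of higher calls by more than 10 percentage points. RLE scaling, the filter of 1 CPM, limma on log2(FPKM + 0.1), the robust spread and leaving out Nfe2l2 and Mafg kept every count within 1.5 times.

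Without single libraries, with fewer samples, counts ranged from 14 to 35 higher and from 0 to 3 lower for T-N2G in vehicle, from 212 to 284 and 63 to 129 in DEM, from 521 to 662 and 380 to 545 for DEM in mock cells, from 756 to 962 and 568 to 748 in T-N2G cells, and from 22 to 51 and 1 to 3 for the difference.

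Camera called 13, 19, 13, 19 and 18 lists in the 5 comparisons, and with an estimated correlation 5, 10, 0, 5 and 9, or 4, 8, 0, 8 and 9 with the replicate block as well. The counts of both T-N2G over mock comparisons include the CNC and small Maf list, which the introduced genes decide. Fry called 8 for T-N2G in vehicle and 9 for the difference as directional, and 8, and 23 for DEM in mock cells, and 11 for the difference as mixed. The Pearson r of the T-N2G effects, 0.694, was 0.737 over genes at 1 CPM and 0.596 to 0.649 without a replicate number. That of the DEM effects, 0.642, was 0.524 to 0.606 without a replicate number. With the block they were 0.696 and 0.644.

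Of 356 named pairs of gene and comparison 335 were called, and none reversed under an alternative. Besides leaving out a single library, 118 kept their call under every alternative, and 116 under those as well. The alternatives behind the 118 include replicates 1 and 2 alone, which leaves out replicate 3 of every group and by itself kept 123. The block and the robust spread kept all 335, RLE scaling 334, library size alone 322, no filter 316, a fit of only the groups compared 242 of the 305 it tested, limma 310 on log2(FPKM + 1) and 317 on log2(FPKM + 0.1), 306 of 324 at 1 FPKM in 3 libraries, and replicates 1 and 2 alone 123. DESeq2 kept 329 and the filter of 1 CPM 333 of the 333 they tested. Depth limits the genes of low level, since 11849 genes had too few fragments to be tested, and Gsta1, Sstr5 and Prl2c3 in mock DEM had 0 fragments and allow only a lower bound. For T-N2G over mock cells in vehicle, simulated with replicate effects like those of the libraries (12408 genes tested), changes of 1.5-fold were recovered for 63 of 100 genes without the block and 91 with it, and those of 2-fold for 85 and 99. The changed genes had a mean of at least 2 CPM, so these values do not cover genes below that level.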

Other observations

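The tests on Hmox1, on the share of cells with a Y chromosome and on imprinted genes were chosen after the results were seen. The test on genes of like level was set before it was run, but for Y-linked genes chosen after their values were seen. Hmox1 rose under DEM in mock cells, which lack small Mafs, from 997 to 2000.0 CPM (log2 1.00, SE 0.20, adjusted p = 0.00753 by edgeR, higher in 3 of 3 pairs). T-N2G material in the mock libraries is argued against, since the Mafg fragments of mock DEM allow a share of at most 0.723%. That share would bring 44.9 CPM, or 4.48% of the rise of 1003 CPM. A route to Hmox1 without small Mafs may exist in these cells and is open, as RNA alone was measured and no protein or binding to DNA.

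The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in T-N2G than in mock cells in 3 of 3 pairs, with log2 fold changes of 0.70, 0.62, 0.46 and 0.54 in vehicle and 0.84, 0.67, 0.45 and 0.87 in DEM, where Ddx3y was called in both (adjusted p = 0.0154 and 0.000612 by edgeR) and Eif2s3y and Uty in DEM (0.0301 and 0.0358). With the replicate block Eif2s3y was called in vehicle as well. Genes of like level had a median of -0.015 in vehicle against 0.58 for the Y-linked genes, which argues against a shift of all genes of low level. A larger share of cells with a Y chromosome in the T-N2G cultures is a candidate explanation, since it needs equal folds. Cochran's Q of the 4 values, by a chi-square approximation on the errors of the fit with the replicate block, gave probabilities of 0.621 in vehicle and 0.205 in DEM (mean folds 1.53 and 1.67), which do not show that the values were equal. Mock and T-N2G cells may thus differ in composition besides T-N2G.

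The imprinted genes Peg10 (log2 1.47, SE 0.17, adjusted p = 0.00197 by edgeR), Cdkn1c (0.84, SE 0.08, adjusted p = 0.000853) and Zdbf2 (-1.78, SE 0.31, adjusted p = 0.0355) differed between T-N2G and mock cells in vehicle. A list of imprinted genes written after this had 41 tested members, of which 4 were called without the block and 11 with it, 6 higher and 5 lower. Without the 5 that prompted the list, Peg10, Cdkn1c, Zdbf2, Peg3 and Igf2, 6 of 36 (16.7%) were called with the block against 6.23% of the 12428 other genes (Fisher's exact test, 2-sided p = 0.0229). Of those 6, however, 3 (Asb4, Sgce and H19) lie within 2 Mb of a prompting gene in the reference annotation GRCm38.p6. Without such neighbours 3 of 32 were called (Fisher's exact test, 2-sided p = 0.449), so whether imprinted genes differ more often than others is open.

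Cyb5a and Cgnl1 had opposite DEM effects, -0.37 and -0.50 in mock and 1.10 and 0.65 in T-N2G cells (log2), with differences of 1.47 and 1.16 (adjusted p = 0.000282 and 0.0122 by edgeR).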
